A study of Mus musculus with 12 samples.

How the data were processed

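Whole lungs without the large airways and trachea (all 5 lobes) had been homogenised in TRIzol, and libraries of polyA RNA, made with a TruSeq-based NEB kit, had been sequenced with paired-end reads of 151 bp on an Illumina NovaSeq instrument, per the labels' protocols. The submitters' processing notes name cutadapt 4.8, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3 and MultiQC 1.20 with the genome build GRCm38. The strand setting and the annotation release were not given in the sources used here. The expected counts were deposited as whole numbers per gene and library, from RSEM per the submitters' processing notes, and their totals differed between libraries. The TPM values were deposited beside them, scaled per library to the same total over all genes, per the file headers. The FPKM values were deposited as a further table, scaled for length and library size, per the file headers. The tables had 55491 entries: 55487 Ensembl genes and 4 reporter or recombinase sequences with a summed count of 0. Gene symbols were those paired with the identifiers in the deposited tables. Coordinates were taken from GENCODE M21 on GRCm38, which held 55141 of the identifiers. The 12 columns were matched to mice through the library names in the labels, and 0 columns were left without a label.

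Differential expression was computed from the expected counts with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by group (minimum count 10, minimum total 15), which left 17909 genes, and 21736 genes had no count in any library. Libraries were scaled with TMM. The 12 libraries entered one quasi-likelihood fit with robust dispersion (glmQLFit) and one group term, with statmod 1.5.0, and each of the 3 comparisons was a two-sided contrast tested with glmQLFTest. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors and 95% confidence intervals of fold changes were taken from the same fit. The common biological coefficient of variation was 0.119. Over the 18 pairs of libraries of one group, chi-square per degree of freedom was 7.97 to 33.2 and Spearman's rho over genes 0.989 to 0.996. CPM values are counts over TMM-scaled library sizes.

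Gene lists of cell types, pathways and technical markers (49 lists with at least 5 measured members, 870 entries, all matched to a symbol) were tested with camera in limma 3.58.1. Camera used log2 CPM (prior count 2) and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 49 lists. Camera with a correlation estimated per list and fry were run as further tests. The mean given for a list is the mean of its genes' log2 fold changes in edgeR. A list's score in a library is the mean of its genes' log2 CPM after centring each gene over the 12 libraries, and differences described as mean log2 CPM are differences of these scores. Members adjusted over the list alone were counted with Benjamini-Hochberg within each list on the p-values of edgeR. Overlap between the changes from day 14 was compared with simulated unchanged groups and with fits that split the day 14 libraries. Exact two-sided permutation tests were used for scores of single lists, where 4 libraries against 4 cannot give a p under 0.0286.

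Comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 largest rises and the 10 largest falls among genes past the threshold, with average log2 CPM of at least 1 and the 4 libraries of one group all above the 4 of the other. Predicted and clone-named genes and pseudogenes were left out, and immunoglobulin and T-cell receptor segments were only counted. Where fewer than 5 genes passed in a direction, the 5 genes of smallest p were named as values. Up to 4 members of each list past the threshold were chosen, and the report prints a part of them, mostly genes that kept their calls with each library left out. The same 19 genes of fibrosis, macrophages, neutrophils, epithelium, endothelium and division were given in every comparison.

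The scripts were tested on simulated data made from the gene means, dispersions and library sizes of all 12 libraries. In 5 simulations over 17741 genes, edgeR recovered 56% of 100 genes changed 1.5-fold (52 to 65%) and 76.6% of 100 genes changed 2-fold (71 to 85%), with 6 false calls per simulation. The unchanged comparison, vehicle against day 14, gave 0.2 calls per simulation. Camera called the list of structural matrix genes, shifted by −0.3 on the log2 scale, in 5 of 5 simulations. It called 0 other lists, with the myofibroblast and smooth muscle lists left out of this count. Genes were drawn independently, without correlation inside lists, so this count does not show how often camera calls unchanged lists in the data.

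Alternatives changed one choice at a time, except that limma-trend on TPM or FPKM changed unit, scaling and test together and that DESeq2 also used its own size factors and left genes out of the adjustment (14077 of 17909 were adjusted over for nanoparticle against vehicle). They were DESeq2 1.42.0 (Wald test), limma-voom, RLE and upper quartile scaling, no filter beyond 1 count, a filter of 1 CPM in 4 libraries, fits without robust dispersion and fits of the 8 libraries compared. Others were limma-trend on log2 TPM with pseudocount 1 or 0.1 and on log2 FPKM with pseudocount 1, a prior count of 0.5, an added threshold of 1 on the log2 fold change, the mouse number as a block, and leaving out each library. Chosen after seeing the data were the fit without both libraries that stood apart (nanoparticle replicate 3 and day 14 replicate 2), the exact permutation test of list scores and a ribosomal RNA covariate.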

Results

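Messenger RNA of whole mouse lungs was sequenced to follow bleomycin lung fibrosis with and without intravenous polymer nanoparticles. Bleomycin, a chemotherapy drug that injures the alveolar lining and leaves a scar, was given by the oropharyngeal route at 0.0125 U per mouse, about 0.5 U/kg. The mice were wild-type C57BL/6J males aged 10 weeks. The nanoparticles, 609.22 ± 15.30 nm in diameter, had a poly(lactide-co-glycolide) core and a surfactant coat of poly(ethylene-alt-maleic anhydride). They were injected behind the eye in phosphate-buffered saline at 2 mg per dose, once a day from day 14 to day 18 (5 doses). The 12 libraries formed 3 groups of 4 mice: lungs taken at day 14 before any treatment, vehicle-treated lungs at day 21 and nanoparticle-treated lungs at day 21. Total expected counts per library ran from 25706260 to 42714693 in the day 14 group, from 28001006 to 36208498 in the vehicle group and from 24138582 to 28910459 in the nanoparticle group. A count of 3 corresponded to 0.0702 to 0.124 counts-per-million (CPM), a floor that covers counting error only. No uninjured lungs were among the samples, so levels are compared with day 14 or with vehicle. They are given in CPM as mean ± SD of the 4 libraries of a group, and changes are given on the log2 scale.

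**Figure D1:**
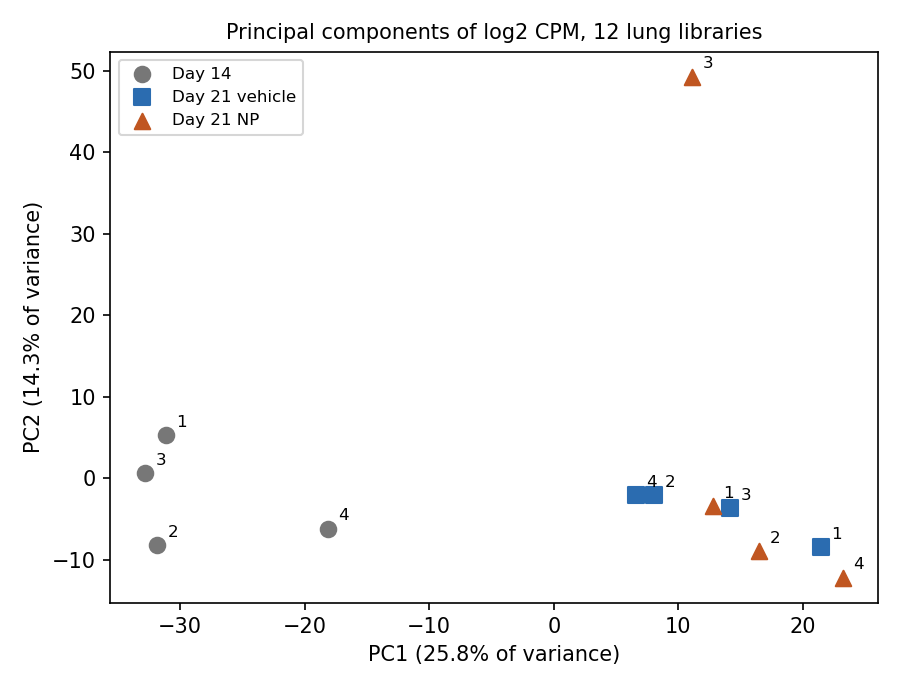
Principal components of log2 CPM over the 12 libraries, one point per library coloured by group, with component 1 (25.8% of the variance) on the horizontal axis and component 2 (14.3%) on the vertical axis. The day 14 libraries lie between −32.8 and −18.1 on component 1 and the day 21 libraries between 6.59 and 23.2, while nanoparticle replicate 3 lies at 49.3 on component 2, where the other 11 libraries lie between −12.2 and 5.31.

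The course of the injury without nanoparticles was read from vehicle-treated lungs at day 21 against lungs at day 14. Over that week the genes of dividing cells, scar matrix, lysosomes and injured epithelium fell, and fewer genes rose. As gene lists these falls passed camera with its preset correlation and did not pass with an estimated one (adjusted p = 0.485 for each of the 4 lists). Col1a1, a chain of type I collagen, fell by 0.94 on the log2 scale (SE 0.15) from 1012 ± 155 to 528 ± 103 CPM, adjusted p = 0.00313. Mki67, a marker of dividing cells, fell by 1.13 on the log2 scale (SE 0.23) from 100.9 ± 0.864 to 46.0 ± 9.98 CPM, adjusted p = 0.0129. Retnla, secreted by macrophages in type 2 responses, fell by 1.85 on the log2 scale (SE 0.18) from 217 ± 44.6 to 60.0 ± 13 CPM, adjusted p = 0.00113. Igfbp3, a binding protein of insulin-like growth factors, rose by 1.80 on the log2 scale (SE 0.25) from 13.7 ± 2.05 to 47.6 ± 12.3 CPM, adjusted p = 0.00315. In edgeR's quasi-likelihood test 1845 of 17909 genes changed, 679 upwards and 1166 downwards (10.3% of genes tested). The 4 libraries of one group lay wholly above or below the 4 of the other for 1661 of these genes. This held for 3200 of all genes tested, 17.9% where chance gives 2.86%. Large rises included the alpha-1A adrenergic receptor gene Adra1a (1.06), Tmem121b (1.42), Phf24 (0.93) and the non-coding Lncppara (1.00). Cyp1a1, an enzyme induced through the aryl hydrocarbon receptor, rose by 2.08 (from 1.89 ± 0.509 to 7.999 ± 3.98 CPM, adjusted p = 0.0214). Its call was lost without day 14 replicate 1 or 3 or vehicle replicate 1 (adjusted p = 0.0592 to 0.0675). Esm1 (1.05), Nrn1 (1.01), Npas2 (1.01) and Snhg11 (0.91) also rose, and each lost its call without any one of 2 to 7 libraries (adjusted p = 0.0509 to 0.111). Day 14 replicates 1 and 3 were among these for each of the 4 genes, and day 14 replicate 2, vehicle replicates 1 to 4 and nanoparticle replicate 1 for some. Large falls included the adhesion gene Chl1 (−1.88), the small G protein Rasd1 (−1.67), the activin antagonist Fst (−1.57) and the transcription factor Etv4 (−1.51). The mitotic genes Pimreg (−1.46) and Kif2c (−1.45) fell with them. So did the growth factor Ereg (−1.72) and Rasl10b (−1.48), which lost their calls without day 14 replicate 3 or vehicle replicate 1 or 3, and Ereg also without day 14 replicate 1 or vehicle replicate 4 (adjusted p = 0.0523 to 0.101). Of 107 immunoglobulin and T-cell receptor segments tested, 9 rose and 0 fell. In GRCm38, with GENCODE M21 gene models, Col1a1 (ENSMUSG00000001506) at 94936224 to 94953042 on chromosome 11 and Retnla (ENSMUSG00000061100) at 48842551 to 48844461 on chromosome 16 are each annotated as protein-coding. In GRCm38, with GENCODE M21 gene models, Igfbp3 (ENSMUSG00000020427) at 7206086 to 7213923 on chromosome 11 and Mki67 (ENSMUSG00000031004) at 135689784 to 135716361 on chromosome 7 are each annotated as protein-coding.

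Scar matrix genes fell as a group. In the structural matrix list 17 of 26 measured members (20 adjusted over the list alone) fell and 0 rose. The structural matrix list averaged −0.50 on the log2 scale (camera adjusted p = 4.66e-11, and adjusted p = 0.485 with an estimated correlation). Its members Col1a2 (−0.69), the collagen-binding Sparc (−0.51) and the elastic fibre gene Fbln2 (−0.53) fell. Fibronectin, Fn1, fell by 0.92 on the log2 scale (SE 0.17) from 2379 ± 358 to 1256 ± 254 CPM, adjusted p = 0.00727. Col3a1, the chain of type III collagen, fell by 0.55 (adjusted p = 0.0366). This call was lost without day 14 replicate 2, 3 or 4 or without vehicle replicate 1, 3 or 4 (adjusted p = 0.0564 to 0.118). Collagen maturation enzymes fell in 11 of 20 (13 adjusted over the list alone). These enzymes averaged −0.33 on the log2 scale (camera adjusted p = 4.14e-07, and adjusted p = 0.485 with an estimated correlation). They included P3h1 (−0.45), which hydroxylates prolines of collagen, its partner Crtap (−0.31) and the cross-linking oxidase Lox (−0.56). Matrix proteases and their inhibitors fell in 6 of 23 (8 adjusted over the list alone). Proteases and inhibitors averaged −0.33 on the log2 scale (camera adjusted p = 0.00155, and adjusted p = 0.508 with an estimated correlation). The protease inhibitor Timp1 fell by 1.56 on the log2 scale (SE 0.22) from 29.2 ± 8.05 to 9.90 ± 1.60 CPM, adjusted p = 0.00275. Myofibroblast genes fell in 2 of 18 (6 adjusted over the list alone). Myofibroblast genes averaged −0.35 on the log2 scale (camera adjusted p = 0.0074, and adjusted p = 0.509 with an estimated correlation). Their list lost its call without day 14 replicate 2 (adjusted p = 0.0544). Acta2, the smooth muscle actin of myofibroblasts, differed by −0.12 (adjusted p = 0.597), and Cthrc1, a gene of scar fibroblasts, by −0.59 (adjusted p = 0.0732, and 0.00621 without vehicle replicate 2). The TGF-beta pathway list averaged −0.19 on the log2 scale (camera adjusted p = 0.0598) and did not pass, with 5 members lower and 1 higher. This list passed without day 14 replicate 1 or 2 or vehicle replicate 4 (adjusted p = 0.0478, 0.0316 and 0.0370). Tgfb1 itself fell by 0.24 (adjusted p = 0.0221), and lost its call without day 14 replicate 3 or vehicle replicate 1, 2 or 3 (adjusted p = 0.0570 to 0.0762). Its activin subunit Inhba (−1.22), the matrix protein Tgfbi (−0.61) and Ccn2 (−1.04) fell.

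Genes of cell division fell without exception in their list. All 27 members of the cell cycle list fell, also adjusted over the list alone. Cell cycle genes averaged −1.05 on the log2 scale (camera adjusted p = 4.32e-22, and adjusted p = 0.485 with an estimated correlation). They included the replication genes Mcm5 (−1.04), Mcm2 (−0.84), Mcm3 (−0.65) and Pcna (−0.48). Genes of transitional epithelium, the keratin 8-high state between alveolar type 2 and type 1 cells, fell in 13 of 18 (16 adjusted over the list alone). Transitional epithelium genes averaged −0.61 on the log2 scale (camera adjusted p = 2.16e-10, and adjusted p = 0.485 with an estimated correlation). The keratin Krt8 fell by 0.50 (from 281 ± 20.2 to 198 ± 22.6 CPM), Krt7 by 0.43 and the growth factor Hbegf by 0.41. The p53 and senescence list fell in 10 of 20 (11 adjusted over the list alone). Its genes averaged −0.35 on the log2 scale (camera adjusted p = 7.91e-06, and adjusted p = 0.485 with an estimated correlation). The cell cycle inhibitor Cdkn1a fell by 0.71, the stress cytokine Gdf15 by 0.90 and the stress sensor Sesn2 by 0.59. Glucocorticoid response genes fell in 4 of 14 (6 adjusted over the list alone), the metal-binding Mt1 by 0.82. Glucocorticoid genes averaged −0.68 on the log2 scale (camera adjusted p = 0.00039, and adjusted p = 0.509 with an estimated correlation). They differed in mean log2 CPM by −0.63 with all libraries and by −0.42 without day 14 replicate 1. Immediate early genes, which answer stimuli and tissue handling quickly, fell in 3 of 17 (7 adjusted over the list alone). Immediate early genes averaged −0.87 on the log2 scale (camera adjusted p = 0.000291, and adjusted p = 0.509 with an estimated correlation). Their score was 1.27 in day 14 replicate 2 and between −0.513 and 0.371 in the other 11 libraries, and without that library the difference of scores was −0.39 in place of −0.71.

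Lysosomal genes and those of SPP1-type and interstitial macrophages were lower at day 21. The alveolar macrophage list did not pass with all libraries (mean −0.16, camera adjusted p = 0.0557, 2 members higher, with Ear1 at 0.76, and 2 lower). It passed without any one of 8 libraries, day 14 replicates 2 to 4, vehicle replicates 3 and 4 and nanoparticle replicates 1, 3 and 4 (adjusted p = 0.0166 to 0.0451). Lysosomal genes fell in 14 of 23 (19 adjusted over the list alone). Lysosomal genes averaged −0.32 on the log2 scale (camera adjusted p = 1.46e-10, and adjusted p = 0.485 with an estimated correlation). Cathepsin S, Ctss, fell by 0.64 and cathepsin D, Ctsd, by 0.64, both lysosomal proteases. Progranulin, Grn, a protein of lysosomes, fell by 0.39. SPP1-type macrophage genes, known from scarred lungs, fell in 11 of 18 (14 adjusted over the list alone). SPP1-type genes averaged −0.51 on the log2 scale (camera adjusted p = 5.98e-08, and adjusted p = 0.508 with an estimated correlation). Cathepsin B, Ctsb, fell by 0.51 and the macrophage marker Cd68 by 0.61. Spp1 itself, osteopontin, fell by 0.95 (adjusted p = 0.0276). It lost its call without day 14 replicate 2 or 3 or without vehicle replicate 1 or 3 (adjusted p = 0.0543 to 0.0825). Scavenger receptors fell in 5 and rose in 1 of 22 members (11 and 2 adjusted over the list alone). Scavenger receptors averaged −0.27 on the log2 scale (camera adjusted p = 0.00136, and adjusted p = 0.508 with an estimated correlation). The lipoprotein receptor Scarb1 fell by 0.59, while the fatty acid receptor Cd36 rose by 0.31. Marco, a receptor that binds particles, differed by −1.16 (adjusted p = 0.116, and 0.00252 without nanoparticle replicate 3, a library that enters the shared fit). Genes of monocytes and interstitial macrophages fell in 6 of 18 (8 adjusted over the list alone), the complement gene C1qb by 0.90. Monocyte genes averaged −0.32 on the log2 scale (camera adjusted p = 0.00744, and adjusted p = 0.509 with an estimated correlation). Their list lost its call without day 14 replicate 2 (adjusted p = 0.0503).

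Genes of the type 2 response fell in 6 of 16 (8 adjusted over the list alone). Type 2 genes averaged −0.39 on the log2 scale (camera adjusted p = 0.00894, and adjusted p = 0.508 with an estimated correlation). With Retnla, the chemokine Ccl8 fell by 1.00 and the interleukin 4 receptor Il4ra by 0.48. The arginase Arg1 fell by 1.23 (adjusted p = 0.0174). Inflammatory cytokines and chemokines fell in 5 of 22 (6 adjusted over the list alone). Inflammatory genes averaged −0.50 on the log2 scale (camera adjusted p = 0.00754, and adjusted p = 0.509 with an estimated correlation). The monocyte attractants Ccl12 and Ccl7 fell by 1.68 and 1.48, from 2.55 ± 0.561 and 1.84 ± 0.767 CPM. Ccl2, another monocyte attractant, fell by 1.18 (adjusted p = 0.0178). Arg1 and Ccl2 each lost their call without day 14 replicate 3 or without vehicle replicate 1 or 3 (adjusted p = 0.0533 to 0.0666). Interferon response genes fell in 8 of 21 (10 adjusted over the list alone), Cxcl10 by 1.32 and Ifit1 by 0.72. Interferon genes averaged −0.41 on the log2 scale (camera adjusted p = 1.41e-05, and adjusted p = 0.509 with an estimated correlation). Il1b, an inflammatory cytokine, differed by −0.15 (adjusted p = 0.9) and the neutrophil gene S100a8 by 0.66 (adjusted p = 0.72).

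Genes of energy metabolism moved by small amounts. Glycolysis genes fell in 7 of 19 (12 adjusted over the list alone), among them Gapdh (−0.49), Ldha (−0.39), Pgam1 (−0.37) and Pgk1 (−0.33). Glycolysis genes averaged −0.22 on the log2 scale (camera adjusted p = 0.000182, and adjusted p = 0.508 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 3 of 30 (10 adjusted over the list alone). Respiratory chain genes averaged −0.11 on the log2 scale (camera adjusted p = 0.000426, and adjusted p = 0.509 with an estimated correlation). Their difference in mean log2 CPM was −0.11 with all libraries and −0.0649 without day 14 replicate 2. The unfolded protein response fell in 2 of 18 (3 adjusted over the list alone). Unfolded protein genes averaged −0.16 on the log2 scale (camera adjusted p = 0.00633, and adjusted p = 0.509 with an estimated correlation). Mitochondrially encoded genes rose in 2 of 13 (2 adjusted over the list alone). Mitochondrial transcripts averaged 0.12 on the log2 scale (camera adjusted p = 0.0156, and adjusted p = 0.509 with an estimated correlation).

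Rises were found in lists of lung, blood and heart muscle cells. Alveolar type 2 cell genes rose in 3 of 18 (10 adjusted over the list alone). Type 2 cell genes averaged 0.17 on the log2 scale (camera adjusted p = 0.003, and adjusted p = 0.509 with an estimated correlation). Slc34a2, a phosphate transporter of these cells, rose by 0.35 (adjusted p = 0.0249). Its call was lost without day 14 replicate 3 or without vehicle replicate 3 or 4 (adjusted p = 0.0517 to 0.0787). The surfactant gene Sftpc differed by 0.23 (adjusted p = 0.0833) and the alveolar type 1 gene Ager by −0.09 (adjusted p = 0.393). Alveolar fibroblast genes rose in 3 of 14 (6 adjusted over the list alone) and fell in 1. Alveolar fibroblast genes averaged 0.25 on the log2 scale (camera adjusted p = 0.00754, and adjusted p = 0.509 with an estimated correlation). The methyltransferase Inmt rose by 0.75 on the log2 scale (SE 0.14) from 544 ± 49.6 to 914 ± 199.6 CPM, adjusted p = 0.0072. The integrin Itga8 rose by 0.57, while the microfibril gene Mfap4 fell by 0.63. The airway genes Cyp2f2 and Tppp3, markers of club and ciliated cells, rose by 0.41 and 0.42, while their list did not pass (camera adjusted p = 0.087, 2 members higher and 1 lower, and 0.0366 without day 14 replicate 2). Pan-endothelial genes averaged 0.15 on the log2 scale (camera adjusted p = 0.0131, and adjusted p = 0.509 with an estimated correlation). The endothelial marker Pecam1 differed by 0.12 (adjusted p = 0.402). With 0 of 16 members called, the endothelial list lost its call without day 14 replicate 1 (adjusted p = 0.0888). B cell genes averaged 0.38 on the log2 scale (camera adjusted p = 0.00754, and adjusted p = 0.662 with an estimated correlation). With 0 of 16 members called, the B cell list lost its call without day 14 replicate 1 or vehicle replicate 1 (adjusted p = 0.0798 and 0.0809). Its difference in mean log2 CPM was 0.40 with all libraries and 0.26 and 0.27 without these. Cardiac muscle genes averaged 0.38 on the log2 scale (camera adjusted p = 0.0321, and adjusted p = 0.623 with an estimated correlation). Their list, with 1 of 13 members higher, lost its call without day 14 replicate 1, vehicle replicate 1 or vehicle replicate 3 (adjusted p = 0.0842, 0.0873 and 0.172). In mean log2 CPM it differed by 0.32 with all libraries, by 0.17 without vehicle replicate 3 and by 0.53 without vehicle replicate 2. Natural killer and cytotoxic genes averaged 0.28 on the log2 scale (camera adjusted p = 0.0428, and adjusted p = 0.7 with an estimated correlation). With 0 of 14 members called, this list lost its call without any one of 6 libraries (adjusted p = 0.0565 to 0.244). These were day 14 replicates 1, 3 and 4, vehicle replicates 1 and 3 and nanoparticle replicate 1. The list differed in mean log2 CPM by 0.30 with all libraries, by 0.16 without day 14 replicate 1 and by 0.48 without day 14 replicate 2.

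In all, 26 of 49 lists passed camera, 7 upwards and 19 downwards, and fry, which asks whether a list's genes move one way without comparing them with other genes, called 12. With an estimated correlation 0 passed, and 4 had an unadjusted p under 0.05. The count of 1845 genes was 719 without day 14 replicate 3, 744 without vehicle replicate 1, 866 without vehicle replicate 3 and 1012 without day 14 replicate 1. RNAs without a poly(A) tail, a sign of library quality, had a score of 0.885 ± 0.999 with vehicle and −0.359 ± 0.86 at day 14. Whether this bears on the changes was not tested. Of 134 called genes chosen by the naming rules 57 lost their call without at least 1 library, and most of these are not printed here, while the genes printed kept theirs unless stated.

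**Figure D2:**
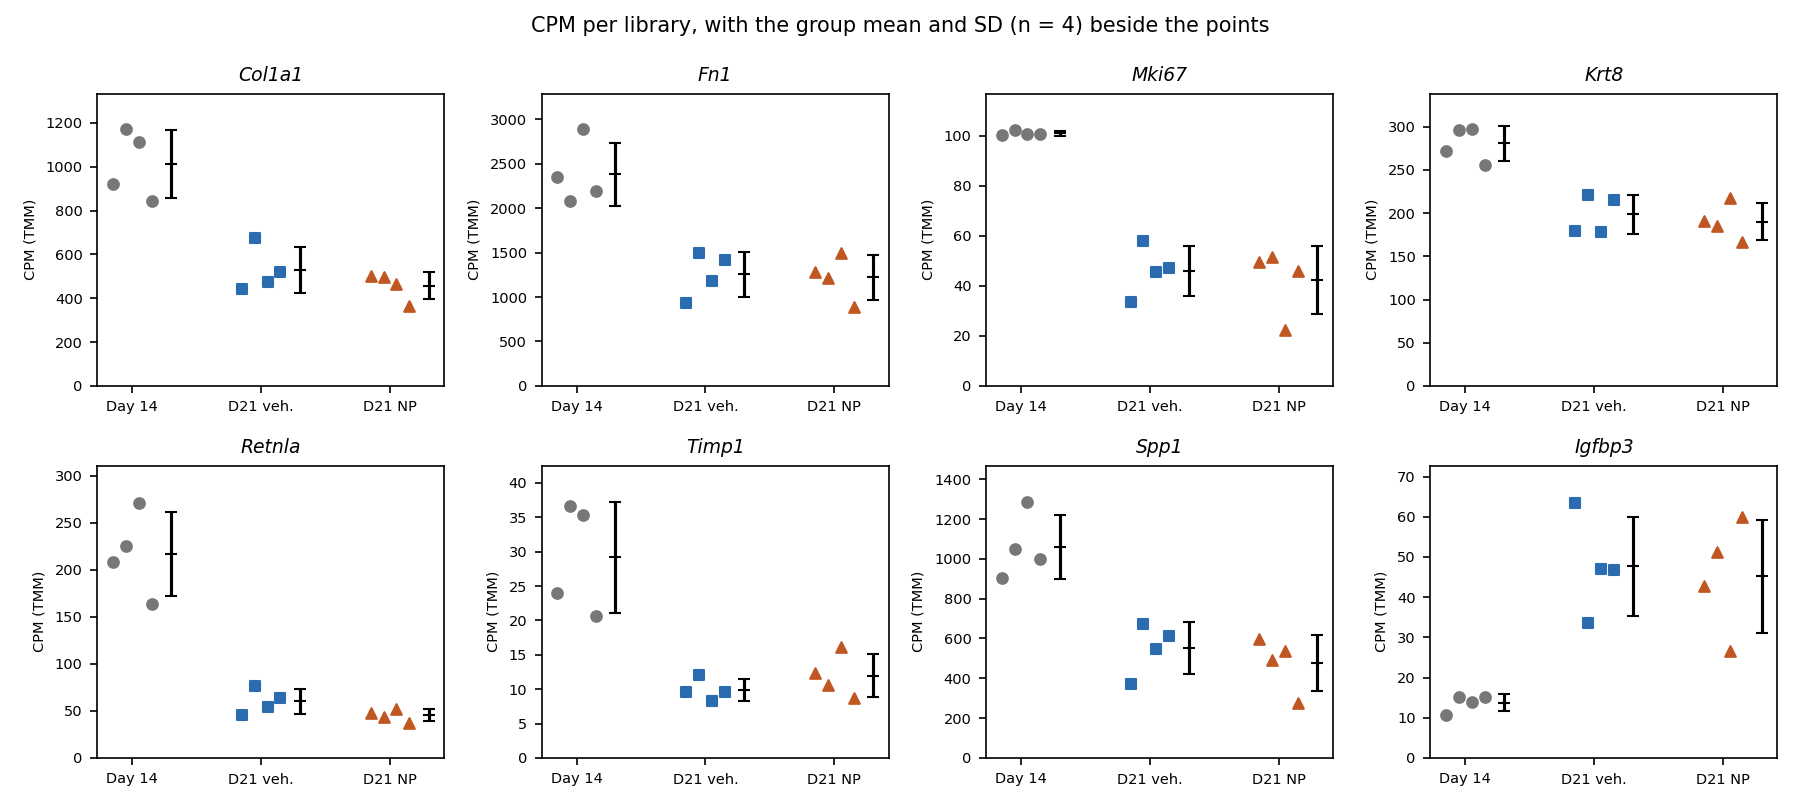
CPM of Col1a1, Fn1, Mki67, Krt8, Retnla, Timp1, Spp1 and Igfbp3 in each of the 12 libraries, with one point per library and the mean ± SD of the 4 libraries of each group. Retnla was 217 ± 44.6 CPM at day 14, 60.0 ± 13 CPM in vehicle-treated and 45.2 ± 6.42 CPM in nanoparticle-treated lungs at day 21.

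The treatment comparison set nanoparticle-treated against vehicle-treated lungs at day 21. No single gene passed the adjusted threshold. By camera with its preset correlation, lists of interferon, inflammatory, monocyte, neutrophil and natural killer cell genes had higher values in the treated lungs, and lists of matrix, airway and respiratory chain genes lower values. With an estimated correlation, and with fry, 0 lists passed. Col1a1 was 458 ± 62.7 CPM with nanoparticles and 528 ± 103 CPM with vehicle (0.866-fold, 95% confidence interval 0.698 to 1.07, adjusted p = 0.999). Fn1 differed by −0.04 (SE 0.17, adjusted p = 0.999). First in rank was Samsn1, an adaptor of blood cells, at 15.7 ± 2.33 against 10.4 ± 0.471 CPM (1.51-fold, 95% confidence interval 1.29 to 1.77, adjusted p = 0.451). In edgeR's quasi-likelihood test 0 of 17909 genes passed. At an unadjusted p under 0.05 there were 762 genes, 431 higher and 331 lower with nanoparticles, where chance gives 895. DESeq2 called 19 genes on the same counts, 17 higher and 2 lower (18 when adjusted over all 17909 genes), and limma called 0 on the counts (voom), on TPM and on FPKM. The 4 libraries of one group lay wholly above or below the 4 of the other for 635 genes, 3.55% where chance gives 2.86%. The median absolute log2 difference over all genes was 0.0707.

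Genes of smallest p in each direction are given as values. Higher with nanoparticles were Was (0.39), the actin regulator of blood cells, and Itgal (0.53), the alpha chain of the leukocyte integrin LFA-1. Ms4a6c (0.44), a monocyte gene, and Acod1 (2.67), the itaconate-making enzyme of activated macrophages, followed, all with an adjusted p of 0.451. Acod1 was at 0.993 ± 0.64 against 0.149 ± 0.0836 CPM. Lower was Mgl2, a lectin of macrophages and dendritic cells in type 2 responses, at 22.4 ± 2.11 against 30.7 ± 2.60 CPM (adjusted p = 0.451). Il1rl1, the interleukin 33 receptor, was at 8.17 ± 0.571 against 10.9 ± 0.65 CPM (adjusted p = 0.476). The non-coding A730063M14Rik (−1.31, adjusted p = 0.851) and the kinase Dmpk (−0.29, adjusted p = 0.867) were also lower. In GRCm38, with GENCODE M21 gene models, Samsn1 (ENSMUSG00000022876) at 75858793 to 76022281 on chromosome 16, Mgl2 (ENSMUSG00000040950) at 70130329 to 70137550 on chromosome 11 and Il1rl1 (ENSMUSG00000026069) at 40429570 to 40465415 on chromosome 1 are each annotated as protein-coding. The scar genes Col3a1 (−0.29), Cthrc1 (−0.26), Acta2 (−0.11), Timp1 (0.27) and Tgfb1 (0.12) had adjusted p of 0.999. So did the macrophage genes Spp1 (−0.21), Arg1 (−0.12) and Cd68 (0.22). Sftpc (−0.12), Ager (−0.07), Krt8 (−0.06), Pecam1 (0.05) and Mki67 (−0.12), markers of alveolar type 2, type 1, transitional, endothelial and dividing cells, had the same adjusted p. Marco (0.47), Ccl2 (0.52), Il1b (0.93) and S100a8 (2.30) differed by more and also had an adjusted p of 0.999. S100a8 was at 322 CPM in nanoparticle replicate 3 and between 8.12 and 30.0 CPM in the other 11 libraries.

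Lists of blood-borne and inflammatory genes had higher values with nanoparticles. RNAs without a poly(A) tail, a sign of library quality, differed between the same groups by −1.41 in mean log2 CPM (exact two-sided permutation p = 0.0857), and with ribosomal RNA as a covariate 342 genes in place of 762 had an unadjusted p under 0.05. Ribosomal RNA was higher in 3 of the 4 vehicle libraries, so the covariate takes up part of the group difference whatever its cause. The drop therefore cannot be assigned to library quality. Interferon response genes were higher in 20 of 21 members. Interferon genes averaged 0.31 on the log2 scale (camera adjusted p = 1.46e-08, and adjusted p = 0.675 with an estimated correlation). In mean log2 CPM they differed by 0.26 with all libraries and by 0.0827 without nanoparticle replicate 1 (adjusted p = 0.00401). Inflammatory cytokines and chemokines were higher in 20 of 22. Inflammatory genes averaged 0.47 on the log2 scale (camera adjusted p = 5.25e-08, and adjusted p = 0.45 with an estimated correlation). Monocyte and interstitial macrophage genes were higher in 18 of 18. Monocyte genes averaged 0.33 on the log2 scale (camera adjusted p = 5.96e-08, and adjusted p = 0.581 with an estimated correlation). Immediate early genes were higher in 17 of 17. Immediate early genes averaged 0.40 on the log2 scale (camera adjusted p = 0.000216, and adjusted p = 0.853 with an estimated correlation). Erythroid and platelet genes were higher in 15 of 15. Erythroid and platelet genes averaged 0.90 on the log2 scale (camera adjusted p = 7.8e-07, and adjusted p = 0.581 with an estimated correlation). Their difference in mean log2 CPM was 0.59 with all libraries and 0.26 without nanoparticle replicate 2 (adjusted p = 0.00151). The beta-globin gene Hbb-bs ranged from 86.3 CPM in nanoparticle replicate 3 to 1424 CPM in nanoparticle replicate 2. Neutrophil genes were higher in 16 of 17. Neutrophil genes averaged 1.54 on the log2 scale (camera adjusted p = 1.79e-05, and adjusted p = 0.765 with an estimated correlation). In mean log2 CPM they differed by 0.85 with all libraries and by 0.18 without nanoparticle replicate 3, where the list lost its call (adjusted p = 0.250). Natural killer and cytotoxic genes were higher in 13 of 14. Natural killer and cytotoxic genes averaged 0.30 on the log2 scale (camera adjusted p = 0.00639, and adjusted p = 0.956 with an estimated correlation). Their list lost its call without nanoparticle replicate 2 or 4 (adjusted p = 0.395 and 0.223). It differed in mean log2 CPM by 0.24 with all libraries, by 0.1 and 0.13 without these and by 0.45 without nanoparticle replicate 3.

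Lists with lower values were those of the respiratory chain, scar matrix, type 2 response, airway, smooth muscle and cell cycle. Oxidative phosphorylation genes were higher in 3 of 30 members and lower in the others. Respiratory chain genes averaged −0.08 on the log2 scale (camera adjusted p = 1.13e-06, and adjusted p = 0.765 with an estimated correlation). Structural matrix genes were higher in 1 of 26. The structural matrix list averaged −0.16 on the log2 scale (camera adjusted p = 4.83e-06, and adjusted p = 0.765 with an estimated correlation). Its difference in mean log2 CPM was −0.15 with all libraries, −0.0708 without vehicle replicate 2, −0.0923 without nanoparticle replicate 4 and −0.24 without vehicle replicate 1, and it passed in each of these fits. Type 2 response genes were higher in 5 of 16. Type 2 genes averaged −0.22 on the log2 scale (camera adjusted p = 0.000257, and adjusted p = 0.45 with an estimated correlation). Smooth muscle and pericyte genes were higher in 1 of 15. Smooth muscle genes averaged −0.11 on the log2 scale (camera adjusted p = 0.00198, and adjusted p = 0.675 with an estimated correlation). Airway epithelium genes were higher in 2 of 20. Airway genes averaged −0.17 on the log2 scale (camera adjusted p = 0.00125, and adjusted p = 0.581 with an estimated correlation). Their call was lost without nanoparticle replicate 1 (adjusted p = 0.0730). Cell cycle genes were higher in 3 of 27. Cell cycle genes averaged −0.15 on the log2 scale (camera adjusted p = 0.00198, and adjusted p = 0.956 with an estimated correlation). In mean log2 CPM they differed by −0.18 with all libraries, by 0.03 without nanoparticle replicate 3 (adjusted p = 0.374) and by −0.0763 without vehicle replicate 2 (adjusted p = 0.323). Without vehicle replicate 1 or nanoparticle replicate 2 the difference was −0.30 and −0.27.

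Adjusted over the list alone, 11 list entries passed, 9 of them higher and 2 lower with nanoparticles. Among monocyte genes they were Treml4 and Ms4a6c (adjusted p = 0.00212), Ly6c2 (0.0079) and the growth factor receptor Csf1r (0.022). The neutrophil attractant Cxcl2 (adjusted p = 0.0494) passed among inflammatory genes, and Ppbp and Itga2b (0.0469) among platelet genes. The macrophage elastase Mmp12 passed in the protease list (adjusted p = 0.0105) and in the SPP1-type list (0.00823), and Mgl2 and Il1rl1 in the type 2 response (0.00255). Treml4, a receptor of patrolling monocytes, was at 11.8 ± 2.38 CPM with nanoparticles and 5.56 ± 0.857 CPM with vehicle, a log2 difference of 1.08. The number of entries was 7 without vehicle replicate 2 and 30 without nanoparticle replicate 4. It was 1 with ribosomal RNA as a covariate, chosen after seeing the data, which also takes up part of the group difference. In all, 13 of 49 lists passed camera, 7 higher and 6 lower, and 20 passed without nanoparticle replicate 4. With an estimated correlation and with fry 0 passed, where 4 and 3 lists had an unadjusted p under 0.05.

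**Figure D3:**
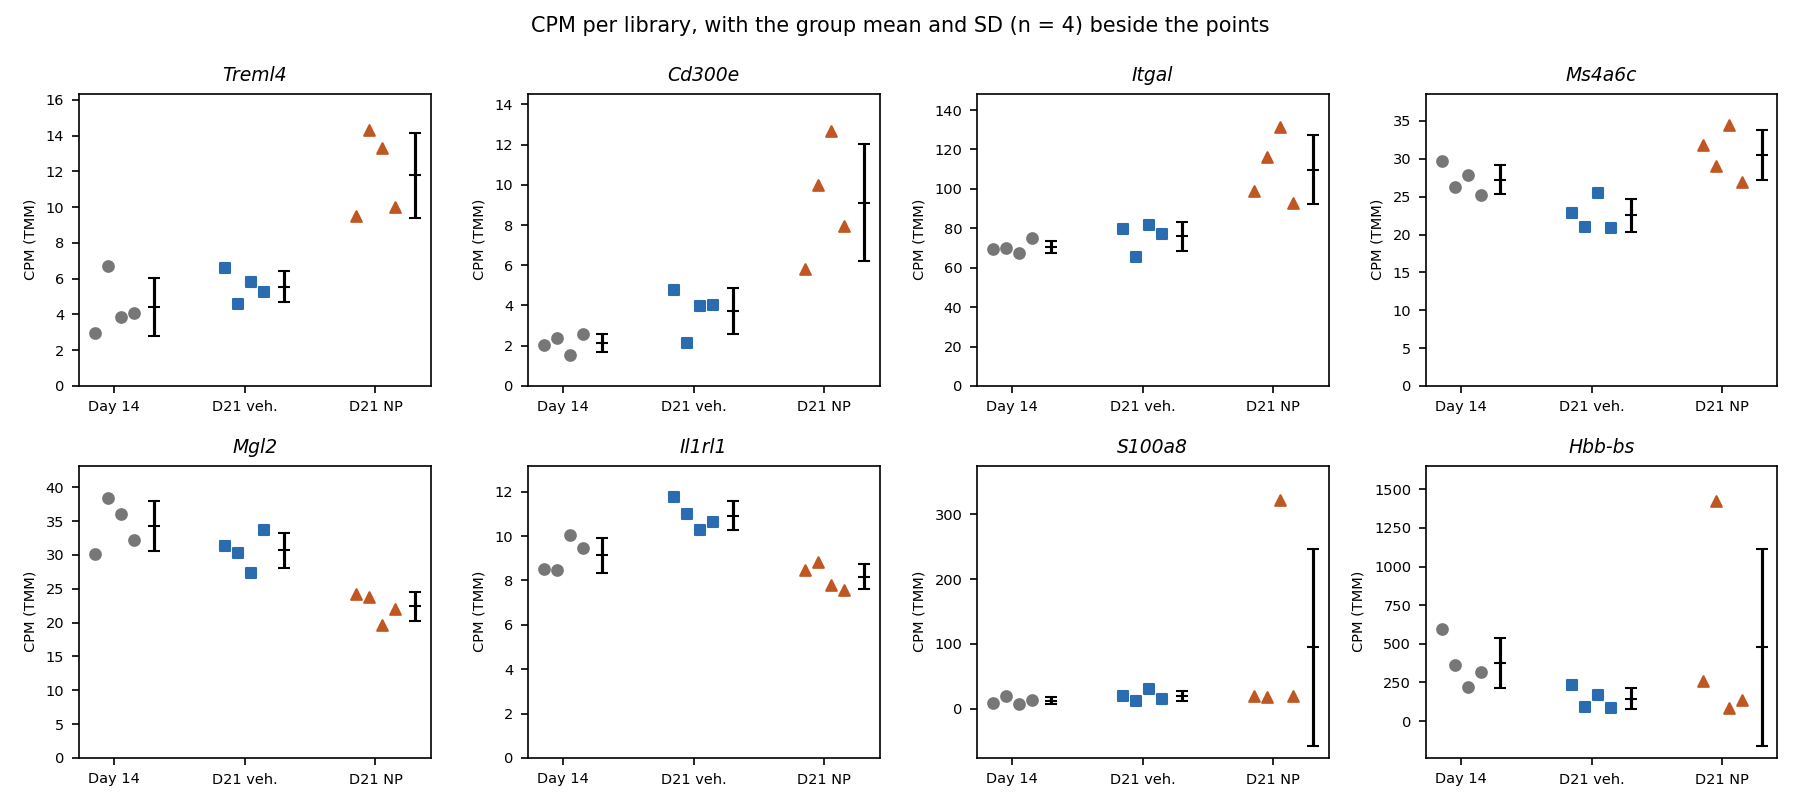
CPM of Treml4, Cd300e, Itgal, Ms4a6c, Mgl2, Il1rl1, S100a8 and Hbb-bs in each of the 12 libraries, with one point per library and the mean ± SD of the 4 libraries of each group. Itgal lay at 109.8 ± 17.6 CPM with nanoparticles and 75.9 ± 7.27 CPM with vehicle, and the highest S100a8 value, 322 CPM, belongs to nanoparticle replicate 3.

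The course with nanoparticles was read from the treated lungs at day 21 against the same day 14 lungs. Scar matrix, cell division, lysosome and injured epithelium genes fell, and the rises included platelet genes and single genes known from monocytes, while the monocyte list did not pass (camera adjusted p = 0.981). With an estimated correlation the lists that fell did not pass either (adjusted p = 0.408, 0.408, 0.591 and 0.408), nor did the erythroid and platelet list (0.633), which lay at −0.04 in mean log2 CPM without nanoparticle replicate 2 and at 0.28 with all libraries. Col1a1 fell by 1.15 on the log2 scale (SE 0.15) from 1012 ± 155 to 458 ± 62.7 CPM, adjusted p = 0.000758. Fn1 fell by 0.96 on the log2 scale (SE 0.17) from 2379 ± 358 to 1221 ± 251 CPM, adjusted p = 0.00399. Retnla fell by 2.26 on the log2 scale (SE 0.18) from 217 ± 44.6 to 45.2 ± 6.42 CPM, adjusted p = 0.000262. Cd300e, a receptor of monocytes, rose by 2.09 on the log2 scale (SE 0.28) from 2.13 ± 0.457 to 9.11 ± 2.91 CPM, adjusted p = 0.000875. In edgeR's quasi-likelihood test 2636 of 17909 genes changed, 1103 upwards and 1533 downwards (14.7%). The groups lay wholly apart for 2225 of them and for 3408 of all genes tested, 19.0% where chance gives 2.86%. Large rises included the monocyte genes Adgre4 (1.73, from 7.13 ± 2.25 to 23.6 ± 6.21 CPM) and Treml4 (1.43) and the sphingosine receptor S1pr5 (1.51). The platelet chemokine Ppbp (1.51), Igfbp3 (1.72) and Cyp1a1 (2.18) also rose, the last 2 with vehicle too (1.80 and 2.08). In vehicle lungs Adgre4 (10.5 to 14.8 CPM) also lay above day 14 (5.03 to 9.24 CPM), so part of its rise was present there. Cd300e (2.11 to 4.76 against 1.53 to 2.57 CPM), S1pr5 (3.10 to 5.11 against 2.04 to 3.54) and Treml4 (4.58 to 6.59 against 2.95 to 6.71) overlapped between vehicle and day 14. Trim30b, of the tripartite motif family, rose by 1.37 and lost its call without day 14 replicate 1 or 3 (adjusted p = 0.0576 and 0.0578). Between nanoparticle and vehicle lungs, Cd300e, Treml4 and S1pr5 had an adjusted p of 0.451 and Adgre4 of 0.876. The interferon-induced Slfn4 rose by 2.73 (adjusted p = 0.0416), with 50.6 CPM in nanoparticle replicate 3 and 5.36 to 11.8 CPM in the other nanoparticle libraries. Without that library the rise was 1.49 (adjusted p = 0.0325). It lost its call without any one of 7 libraries, the day 14 libraries, vehicle replicates 1 and 2 and nanoparticle replicate 1 (adjusted p = 0.0558 to 0.111). The myeloid Ifitm6 rose by 2.60 (adjusted p = 0.025), with 29.6 CPM in nanoparticle replicate 3 and 3.77 to 6.19 CPM in the others, and the rise was 1.45 without it (adjusted p = 0.00278). Without day 14 replicate 1 or 3 its call was lost (adjusted p = 0.0790 and 0.0765). Large falls included the mitotic genes Pbk (−1.81), Iqgap3 (−1.78), Cdk1 (−1.71), Tpx2 (−1.60) and Ube2c (−1.59), with Pimreg (−1.71), Ckap2 (−1.62), Chl1 (−1.74) and Etv4 (−1.62). Of 107 immunoglobulin and T-cell receptor segments tested, 13 rose and 1 fell. In GRCm38, with GENCODE M21 gene models, Cd300e (ENSMUSG00000048498) at 115051917 to 115062177 on chromosome 11 and Treml4 (ENSMUSG00000051682) at 48264295 to 48275360 on chromosome 17 are each annotated as protein-coding.

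Structural matrix genes fell in 22 of 26 (23 adjusted over the list alone). The structural matrix list averaged −0.66 on the log2 scale (camera adjusted p = 1.86e-14, and adjusted p = 0.408 with an estimated correlation). Col1a2 fell by 0.91, Col3a1 by 0.84 (from 1889 ± 227 to 1058 ± 209 CPM), Sparc by 0.60 and Fbln2 by 0.69. Collagen maturation enzymes fell in 13 of 20 (15 adjusted over the list alone), among them the cross-linking oxidase Loxl2 (−0.72) and the procollagen protease Adamts2 (−0.75). These enzymes averaged −0.37 on the log2 scale (camera adjusted p = 1.13e-07, and adjusted p = 0.327 with an estimated correlation). Matrix proteases and inhibitors fell in 9 of 23 (9 adjusted over the list alone), Timp1 by 1.28. Proteases and inhibitors averaged −0.14 on the log2 scale (camera adjusted p = 0.00818, and adjusted p = 0.591 with an estimated correlation). They differed in mean log2 CPM by −0.23 with all libraries and by −0.40 without nanoparticle replicate 3. Myofibroblast genes fell in 7 of 18 (9 adjusted over the list alone), among them Cthrc1 (−0.86) and the actin-binding Tagln (−0.40). Myofibroblast genes averaged −0.40 on the log2 scale (camera adjusted p = 0.00137, and adjusted p = 0.591 with an estimated correlation). Acta2 differed by −0.22 (adjusted p = 0.266) and Tgfb1 by −0.11 (adjusted p = 0.205). The TGF-beta pathway list averaged −0.19 on the log2 scale (camera adjusted p = 0.101) and did not pass, where without nanoparticle replicate 2 it did (adjusted p = 0.0414).

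All 27 cell cycle genes fell, also adjusted over the list alone, Mki67 by 1.25 and Mcm2 by 0.88. Cell cycle genes averaged −1.21 on the log2 scale (camera adjusted p = 8.45e-23, and adjusted p = 0.408 with an estimated correlation). Transitional epithelium genes fell in 12 of 18 (15 adjusted over the list alone), with the keratins Krt8 (−0.56), Krt7 (−0.51) and Krt19 (−0.46). Transitional epithelium genes averaged −0.56 on the log2 scale (camera adjusted p = 1.61e-08, and adjusted p = 0.408 with an estimated correlation). The p53 and senescence list fell in 11 of 20 (12 adjusted over the list alone), its zinc finger gene Zmat3 by 0.53. Its genes averaged −0.34 on the log2 scale (camera adjusted p = 7.04e-05, and adjusted p = 0.408 with an estimated correlation). Glucocorticoid response genes fell in 4 of 14 (4 adjusted over the list alone), with the metal-binding Mt1 (−0.88) and Mt2 (−1.12). Glucocorticoid genes averaged −0.62 on the log2 scale (camera adjusted p = 0.00249, and adjusted p = 0.616 with an estimated correlation). Their difference in mean log2 CPM was −0.58 with all libraries and −0.37 without day 14 replicate 1. Glycolysis genes fell in 8 of 19 (8 adjusted over the list alone) and rose in 1. Glycolysis genes averaged −0.14 on the log2 scale (camera adjusted p = 0.00701, and adjusted p = 0.591 with an estimated correlation). Oxidative phosphorylation genes fell in 13 of 30 (16 adjusted over the list alone), with the respiratory chain subunits Cox7a2 (−0.40) and Ndufa1 (−0.45). Respiratory chain genes averaged −0.20 on the log2 scale (camera adjusted p = 4.42e-08, and adjusted p = 0.591 with an estimated correlation). Mitochondrially encoded genes rose in 4 of 13 (5 adjusted over the list alone), with mt-Nd2 (0.36) and mt-Nd5 (0.42). Mitochondrial transcripts averaged 0.14 on the log2 scale (camera adjusted p = 0.00818, and adjusted p = 0.591 with an estimated correlation). Their difference in mean log2 CPM was 0.14 with all libraries and 0.21 without nanoparticle replicate 3. The unfolded protein response fell in 1 of 18 (0 adjusted over the list alone). Unfolded protein genes averaged −0.12 on the log2 scale (camera adjusted p = 0.0417, and adjusted p = 0.669 with an estimated correlation). Their list lost its call without day 14 replicate 3 or 4 or nanoparticle replicate 1, 2 or 4 (adjusted p = 0.05 to 0.161), and without nanoparticle replicate 1 its difference in mean log2 CPM was −0.0705 in place of −0.12.

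Lysosomal genes fell in 15 of 23 (17 adjusted over the list alone). Lysosomal genes averaged −0.30 on the log2 scale (camera adjusted p = 1.61e-08, and adjusted p = 0.591 with an estimated correlation). SPP1-type macrophage genes fell in 7 of 18 (11 adjusted over the list alone). SPP1-type genes averaged −0.42 on the log2 scale (camera adjusted p = 3.94e-05, and adjusted p = 0.591 with an estimated correlation). Spp1 fell by 1.16 on the log2 scale (SE 0.23) from 1060 ± 162 to 476 ± 139.9 CPM, adjusted p = 0.00871. Type 2 response genes fell in 8 of 16 (9 adjusted over the list alone). Type 2 genes averaged −0.61 on the log2 scale (camera adjusted p = 7.53e-05, and adjusted p = 0.327 with an estimated correlation). The arginase Arg1 fell by 1.35, Ccl8 by 1.21, Mgl2 by 0.61 and the mucin Muc5ac by 1.11. Scavenger receptors fell in 4 of 22 (10 adjusted over the list alone) and rose in 1, with Scarb1 at −0.45 and Cd36 at 0.42. Scavenger receptors averaged −0.21 on the log2 scale (camera adjusted p = 0.00581, and adjusted p = 0.591 with an estimated correlation). Monocyte genes averaged 0.02 on the log2 scale (camera adjusted p = 0.981) and did not pass, with Treml4 and Ly6c2 (0.90) higher and 4 members lower. Interferon genes averaged −0.11 on the log2 scale (camera adjusted p = 0.182) and did not pass, while Cxcl10 fell by 0.89. Without nanoparticle replicate 1 the interferon list passed, at −0.32 in mean log2 CPM (adjusted p = 2.19e-05). Il1b differed by 0.78 (adjusted p = 0.413) and S100a8 by 2.96 (adjusted p = 0.0861). Ccl2 differed by −0.66 (adjusted p = 0.118, and 0.0469 without day 14 replicate 1). Cd68 (−0.39, adjusted p = 0.0613) and Marco (−0.68, adjusted p = 0.317) passed without nanoparticle replicate 3 (adjusted p = 0.0138 and 0.00127), and Cd68 also without vehicle replicate 1 (adjusted p = 0.0461).

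Rises came from lists of blood and resident cells. Erythroid and platelet genes rose in 6 of 15 (6 adjusted over the list alone), with the platelet glycoproteins Gp5 (1.06) and Gp1bb (1.80). Erythroid and platelet genes averaged 0.63 on the log2 scale (camera adjusted p = 0.0288, and adjusted p = 0.633 with an estimated correlation). Their list lost its call without day 14 replicate 3 (adjusted p = 0.0630). In mean log2 CPM it differed by 0.28 with all libraries, by 0.12 without that library and by −0.04 without nanoparticle replicate 2 (adjusted p = 0.366), and by 0.56 without nanoparticle replicate 3. Natural killer and cytotoxic genes rose in 3 of 14 (7 adjusted over the list alone). Natural killer and cytotoxic genes averaged 0.57 on the log2 scale (camera adjusted p = 0.00167, and adjusted p = 0.633 with an estimated correlation). B cell genes rose as a list, with 0 of 16 members called. B cell genes averaged 0.59 on the log2 scale (camera adjusted p = 0.000877, and adjusted p = 0.633 with an estimated correlation). Neutrophil genes rose in 0 of 17 (9 adjusted over the list alone). Neutrophil genes averaged 1.77 on the log2 scale (camera adjusted p = 0.00701, and adjusted p = 0.648 with an estimated correlation). Plasma cell genes rose in 1 of 16 (1 adjusted over the list alone), the regulator Irf4 by 0.45, and fell in 1, the syndecan Sdc1. Plasma cell genes averaged 0.92 on the log2 scale (camera adjusted p = 0.00818, and adjusted p = 0.591 with an estimated correlation). Without nanoparticle replicate 3 the neutrophil and plasma cell lists lost their calls (adjusted p = 0.234 and 0.0895), and their differences in mean log2 CPM were 0.39 in place of 1.05 and 0.42 in place of 0.74. Pan-endothelial genes rose in 1 of 16 (1 adjusted over the list alone), the angiopoietin receptor Tek by 0.39. Pan-endothelial genes averaged 0.19 on the log2 scale (camera adjusted p = 0.00701, and adjusted p = 0.591 with an estimated correlation). Tek lost its call without nanoparticle replicate 4 (adjusted p = 0.0549). Alveolar fibroblast genes rose in 4 of 14 (6 adjusted over the list alone) and fell in 1, with Inmt (0.75) and Itga8 (0.57) among the rises. Alveolar fibroblast genes averaged 0.26 on the log2 scale (camera adjusted p = 0.00891, and adjusted p = 0.591 with an estimated correlation). Type 2 cell genes averaged 0.12 on the log2 scale (camera adjusted p = 0.0917) and did not pass, while Slc34a2 rose by 0.37. Without day 14 replicate 1 or nanoparticle replicate 4 this list passed (adjusted p = 0.0328 and 0.0280). Sftpc (0.11, adjusted p = 0.385), Ager (−0.15, adjusted p = 0.116) and Pecam1 (0.17, adjusted p = 0.198) did not pass.

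In all, 23 of 49 lists passed camera, 8 upwards and 15 downwards, and fry called 12. With an estimated correlation 0 passed, and 5 had an unadjusted p under 0.05. The count of 2636 genes was 1363 without day 14 replicate 3, 1384 without nanoparticle replicate 4, 1570 without day 14 replicate 1 and 1625 without nanoparticle replicate 2, and 1672 with only the 8 libraries compared in the fit. Of 143 called genes chosen by the naming rules 43 lost their call without at least 1 library, and most of these are not printed, while the genes printed kept theirs unless stated.

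**Figure D4:**
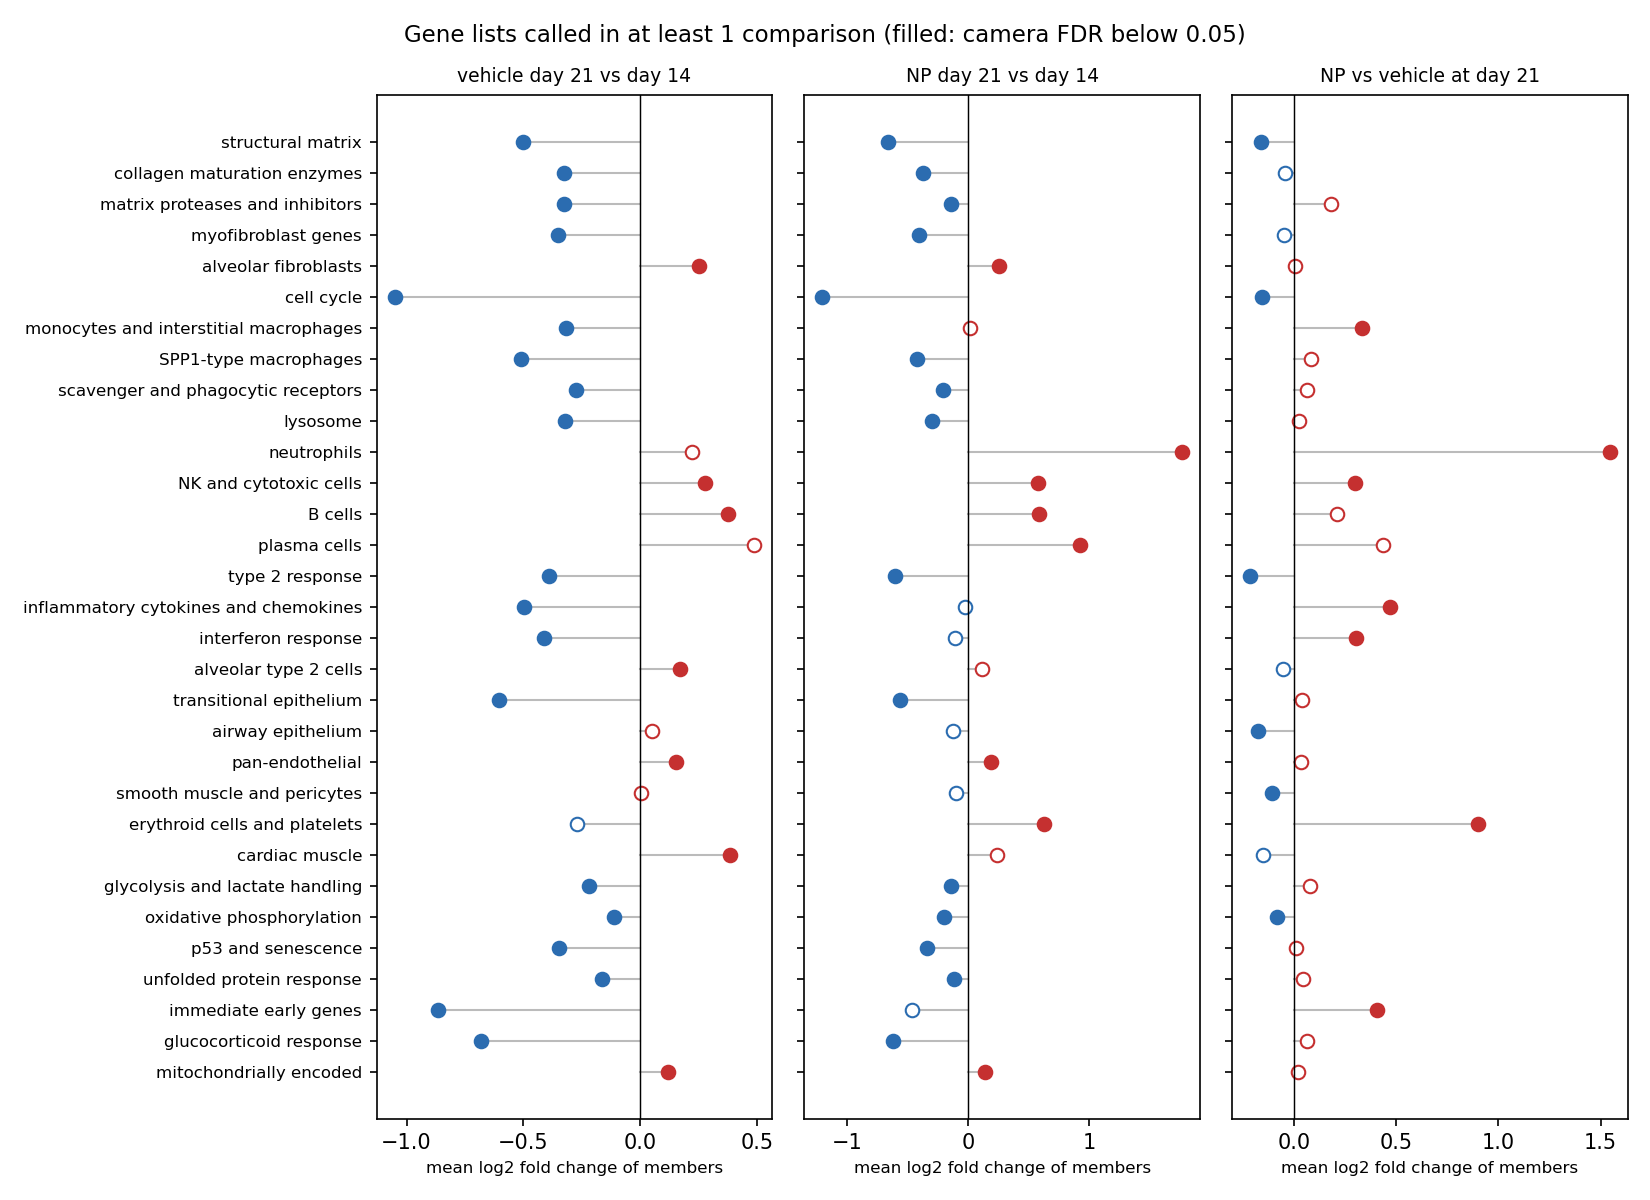
Mean log2 difference of the 31 gene lists called in at least 1 of the 3 comparisons, one panel per comparison, with filled points for lists of camera adjusted p under 0.05 and open points for the others. The cell cycle list lies at −1.05 and −1.21 in the comparisons with day 14 and at −0.15 between nanoparticle and vehicle lungs.

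The changes from day 14 with vehicle and with nanoparticles overlapped. Between them 506 genes rose in both, 929 fell in both and 0 moved in opposite directions past the threshold. Lists of those sizes drawn independently would share 41.8 rising and 99.8 falling genes. Among the shared falls were Col1a1, Fn1, Mki67, Krt8, Retnla and Timp1, and among the shared rises Igfbp3, Inmt and Itga8. A further 410 genes were called with vehicle alone and 1201 with nanoparticles alone, where the direct comparison of both day 21 groups called 0 genes. Both changes rest on the same 4 day 14 libraries. In 20 simulations all 12 libraries were drawn from the day 14 means, with no gene changed. Each comparison then called at most 1 gene, so the 0 shared genes were fixed in advance and do not test the shared libraries. The correlation of log2 fold changes across genes was 0.493 in the simulations (0.440 to 0.559) and 0.794 in the data. The covariance was 0.0222 in the simulations and 0.0994 in the data, a difference of 0.0772. In 6 fits that split the day 14 libraries so that each change used 2 of its own, 201 to 411 genes were shared. Of these, 30 to 91 rose (1.69 to 6.34 expected) and 171 to 320 fell (12.7 to 24.9 expected). The correlations across genes, which are not independent replicates, were then 0.427 to 0.514 and the covariances 0.0700 to 0.0811.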

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

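The 3 tests of nanoparticle replicate 3 reported in this part were chosen after its values were seen. In groups of 4 libraries, a value was listed when the gap between the most extreme library and its nearest neighbour exceeded Dixon's 95% critical value. Chance lists about 1 in 20 groups, which is 16.65 of the 333 groups tested, and 23 were listed. Of these, 10 were values of nanoparticle replicate 3 and 1 of day 14 replicate 2. The total count, given in units of 1000000, was 42.7 in day 14 replicate 1 and 25.7 to 27.9 in the other day 14 libraries.

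In nanoparticle replicate 3 the neutrophil score was 2.65 (−0.127 to 0.0416 in the other nanoparticle libraries) and the cell cycle score −1.12 (−0.353 to −0.203). The lymphatic endothelium score was 0.33 (−0.233 to −0.171), the glycolysis score 0.175 (−0.11 to −0.0723) and the NRF2 oxidative stress score 0.15 (−0.0393 to −0.0327). In the same library S100a8 was at 322 CPM (18.0 to 19.9 in the other nanoparticle libraries), Slfn4 at 50.6 CPM, Ifitm6 at 29.6 CPM, Marco at 11.7 CPM (2.5 to 3.27) and Cthrc1 at 6.52 CPM (4.53 to 4.67).

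Neutrophil and plasma cell genes were high together in nanoparticle replicate 3, with Ly6g at 11.5 CPM (at most 0.616 in the other 11 libraries), Ighm at 653 CPM and Jchain at 131 CPM. Bone marrow carried in would bring haemoglobin, which lay 1.74 below the median of the other 11 libraries (−1.74 on the log2 scale). This gives no sign of marrow, but haemoglobin scores ran from −1.41 to 2.64 in the other 11 libraries. A low value in 1 library therefore does not exclude it. Blood left in the lung would also bring haemoglobin, but platelet genes, likewise from blood, had a score of 0.716 in this library (at most 0.278 in vehicle libraries), so blood stays open. Lymphoid tissue would bring B and T cell genes, whose mean score lay at −0.449 relative to that median, which argues against it. The source of these transcripts stays open, the design names nothing that sets this mouse apart, and no biological explanation was tested.

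Elsewhere among nanoparticle libraries, replicate 4 had the lowest structural matrix score (−0.459 against −0.24 to −0.195) and alveolar type 2 score (−0.0603 against 0.0383 to 0.0535). Replicate 1 had an interferon response score of 0.571 (−0.202 to −0.0858 in the others), and replicate 2 had Hbb-bs at 1420 CPM (86.3 to 261). In vehicle libraries, replicate 4 had an oxidative phosphorylation score of 0.0268 (−0.0228 to −0.0165) and Tgfb1 at 82.5 CPM (78.4 to 79.0). Vehicle replicate 1 had an immediate early score of −0.00592 (−0.513 to −0.43), and replicate 2 had Ifitm6 at 2.92 CPM (3.38 to 3.44) and Dmpk at 54.9 CPM (47.3 to 48.4). At day 14, replicate 3 had a complement score of 0.264 (0.123 to 0.145) and an erythroid and platelet score of −0.483 (0.14 to 0.201). Dmpk was at 58.7 CPM in day 14 replicate 2 (47.4 to 48.4).

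The change from day 14 differed between the nanoparticle and vehicle lungs for 13 lists by camera with the preset correlation, and for 0 with an estimated correlation. Nanoparticle minus vehicle, the mean log2 difference was 1.54 for neutrophils, 0.899 for erythroid cells and platelets, 0.468 for inflammatory cytokines and chemokines and 0.405 for immediate early genes. It was 0.334 for monocytes and interstitial macrophages, 0.305 for the interferon response and 0.297 for natural killer and cytotoxic cells. It was −0.215 for the type 2 response, −0.173 for airway epithelium, −0.159 for structural matrix and −0.155 for the cell cycle. The smallest differences were −0.107 for smooth muscle and pericytes and −0.0832 for oxidative phosphorylation.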

How the results depend on the processing

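The alternatives chosen after seeing the data were leaving out both libraries that stood apart, the exact permutation of list scores and the ribosomal RNA covariate. Values of lists are differences of mean log2 CPM, and where a value changed with a setting the cause was not tested. The 1845 genes of vehicle against day 14 and the 2636 of nanoparticle against day 14 became 220 and 311 with an added threshold of 1 on the log2 fold change, which removes genes by construction. They became 1066 and 1626 with log2(TPM + 1), 1011 and 1590 with log2(TPM + 0.1) and 1089 and 1632 with log2(FPKM + 1). With only the 8 libraries compared, the second count was 1672. Upper quartile scaling gave 888 rises and 934 falls and the CPM filter 854 and 1078, where vehicle against day 14 had 679 and 1166. Nanoparticle against vehicle gave 0 genes with edgeR (762 at an unadjusted p under 0.05), 19 with DESeq2 and 0 with limma-voom, TPM or FPKM. Its list entries adjusted over the list alone, 11 with edgeR, numbered 7 with log2(TPM + 1), 7 with log2(TPM + 0.1), 22 without both libraries and 1 with the covariate. Camera's lists numbered 13, 26 and 23 (nanoparticle against vehicle, vehicle against day 14, nanoparticle against day 14). With an estimated correlation 0 each passed (4, 4 and 5 at an unadjusted p under 0.05). With fry 0, 12 and 12 did (3, 22 and 19). With the exact permutation 0 each did (3, 17 and 13, smallest adjusted p = 0.467, 0.0824 and 0.108). Its p cannot fall under 0.0286, so over 49 lists that 0 was nearly fixed in advance. Without both libraries 19, 34 and 28 lists passed camera. Genes shared by both changes from day 14 numbered 1435, and 399, 411, 201, 362, 239 and 282 when vehicle was compared with day 14 libraries 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4 and nanoparticles with the others, where each change rests on fewer libraries. For vehicle against day 14, Il1b (−0.15) turned to 0.159 with limma-voom, 0.0128 with log2(TPM + 1), 0.0324 with log2(TPM + 0.1), 0.0156 with log2(FPKM + 1) and 0.511 without both libraries. Acta2 (−0.12) turned to 0.0153, 0.0155, 0.0302 and 0.0437 with the last 4 of these settings. For nanoparticle against vehicle without both libraries, Marco (0.47) turned to −0.326, S100a8 (2.30) to −0.00908, Mki67 (−0.12) to 0.0926 and the cell cycle list (−0.18) to 0.0342. The covariate turned Fn1 (−0.04) to 0.00486 and Arg1 (−0.12) to 0.105, and the TGF-beta pathway list (0.000578) was −0.00112 with 8 libraries. Leaving out 1 library at a time gave 0 genes in each fit for nanoparticle against vehicle, 719 to 2162 and 1363 to 2934 genes for the changes from day 14, 13 to 20 lists and 7 to 30 list entries for nanoparticle against vehicle. Over these fits, nanoparticle against vehicle ranged from −0.161 to 0.0842 for Fn1, −0.406 to 0.0074 for Cthrc1, −0.301 to 0.0886 for Arg1, −0.0037 to 0.115 for Pecam1, −0.245 to 0.0931 for Mki67, −0.326 to 0.704 for Marco and −0.00882 to 2.64 for S100a8. The TGF-beta pathway list ranged from −0.0163 to 0.0227 and the cell cycle list from −0.301 to 0.0341. Vehicle against day 14 ranged from −0.463 to 0.506 for Il1b and −0.224 to 0.0435 for Acta2, and nanoparticle against day 14 from −0.042 to 0.556 for the erythroid and platelet list. With each library left out in turn, 77 of the 134 named genes called in vehicle against day 14 and 100 of 143 in nanoparticle against day 14 stayed past the threshold each time, as did 20 of 26, 19 of 23 and 9 of 13 lists (the last for nanoparticle against vehicle). Of 18 lists called in no comparison, 17 besides the TGF-beta pathway had adjusted p of 0.0997 to 0.933 for nanoparticle against vehicle. In 323 alternatives their difference changed sign in 38, over 15 lists, and 12 were called. RLE and upper quartile scaling moved the median of all genes by at most 0.024. With the mouse number as a replicate block there were 0, 1673 and 2419 genes, 13, 27 and 22 lists and 8 list entries, and the erythroid and platelet list of nanoparticle against day 14 lost its call (adjusted p = 0.0654). The labels do not say whether mice of different groups with the same number share anything else. After group means were removed, the 12 same-number pairs of libraries correlated at −0.0744 to 0.148 over genes (mean 0.0208, 36 other pairs −0.00689), and 4 of 12 libraries matched their own number best. Depth limited values under 0.0702 to 0.124 CPM, which is 3 counts per library.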

Other observations

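The genes of non-classical monocytes, the poly(A) comparison and their tests were chosen after the values were seen, and the counts over other splits of the libraries were planned. DESeq2, an alternative test, called 19 genes between nanoparticle and vehicle lungs, 17 higher and 2 lower, and those named here were chosen after their values were seen. The adjusted p in DESeq2 ran from 0.00339 for Samsn1, Itgal, Cd300e and Treml4 to 0.0492 for Zfp729a, where edgeR gave 0.451 for the first 4. DESeq2 adjusted over 14077 genes after its own filter and edgeR over 17909, and over all 17909 genes DESeq2 called 18. Over the other settings the adjusted p ran from 0.106 to 1 for Samsn1 and Itgal, from 0.209 to 1 for Treml4 and from 0.253 to 1 for Cd300e. Higher with nanoparticles were, among others, Was, Ptprc, S1pr5, Fyb, Mmp12, Ms4a6c, Clec4a1, I830077J02Rik, Oas3, Adgre4 and 9930111J21Rik2. Lower were Mgl2 and Il1rl1. The groups lay wholly apart for 17 of the 19.

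Treml4, Cd300e, S1pr5 and Adgre4 are known from non-classical monocytes, which patrol small vessels. Cd300e was at 9.11 ± 2.91 CPM with nanoparticles and 3.72 ± 1.13 CPM with vehicle (log2 difference 1.29), S1pr5 at 7.87 ± 0.701 and 4.29 ± 0.953 CPM (0.88) and Adgre4 at 23.6 ± 6.21 and 12.8 ± 1.80 CPM (0.88). A list of 15 such genes, written after Treml4 and Cd300e had been seen, had a score of 0.399 ± 0.196 with nanoparticles and −0.148 ± 0.142 with vehicle (SD, n = 4). The difference of 0.546 was shown by 4 of 4 nanoparticle libraries, each above all vehicle libraries, by an exact two-sided permutation test (p = 0.0286, the smallest this design can give, and 0.107 adjusted over 5 lists). All 15 genes were measured in these lungs and 4 of them (Treml4, Ace, Cx3cr1 and Nr4a1) are also in the monocyte list. The most abundant were Ace (1217 ± 179.8 against 1075 ± 116 CPM), which endothelial cells also express, and Itgal (109.8 ± 17.6 against 75.9 ± 7.27 CPM). In the same exact test 8 genes of classical monocytes differed by 0.346 (p = 0.0857, adjusted 0.107), 8 platelet genes by 0.561 (p = 0.0857, adjusted 0.107) and haemoglobin genes by 0.913 (p = 0.514).

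Of the 15 genes, Treml4, Cd300e, Adgre4, Itgal and Clec4a1 had been seen among the genes DESeq2 called, so a difference of the whole list was built in and its p says nothing about the other 10. Blood left in the lung stays open. Haemoglobin lay below the highest vehicle library in nanoparticle replicates 3 and 4, and the other 10 genes lay above all vehicle libraries in 1 of these 2 (replicate 3). Platelet genes, also from blood, were higher in these 2 libraries (scores 0.716 and 0.727) than in any vehicle library (at most 0.278). Without nanoparticle replicate 3 the 10 genes differed by 0.342 (0.379 with it), more than the vehicle SD of 0.105. This argues against that library alone making the difference of the 10 genes. Of the 3 remaining nanoparticle libraries, 2 lay above all vehicle libraries. A rise of leukocytes in general stays open as well. The 8 other leukocyte lists differed by a median of 0.128 (SD 0.279), and the difference of 0.379 of the 10 genes lay within that spread of it (exact two-sided permutation p = 0.0571). The 8 lists were T cells (0.092), B cells (0.164), natural killer cells (0.244), dendritic cells (−0.0423), mast cells and basophils (0.0402), alveolar macrophages (0.0561), plasma cells (0.276) and neutrophils (0.849, and 0.179 without nanoparticle replicate 3). The planned list of monocytes and interstitial macrophages differed by 0.311. The difference was found and tested on the same 8 libraries, and a change within monocytes in place of their number was not tested.

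The ribosomal RNA gene CT010467.1 was at 6806, 4363 and 6655 CPM in vehicle replicates 1, 2 and 4, at 2440 CPM in vehicle replicate 3 and at 2574 to 3798 CPM in the other 8 libraries. Lars2 was at 421, 200 and 260 CPM in the same 3 libraries and at 114 CPM in vehicle replicate 3. Against the other 9 libraries, RNAs without a poly(A) tail were higher in these 3 by a median of 1.58 on the log2 scale (Rn7s1 2.74, Rn7s2 1.82, Rmrp 1.58, Rn7sk 1.53, Rpph1 0.858), where CT010467.1 differed by 1.01 and Lars2 by 1.05. Their score was 2.02 and 1.297 in vehicle replicates 1 and 4, above the other libraries, but 0.513 in vehicle replicate 2, under the 0.576 of day 14 replicate 1. Incomplete removal of RNA without a poly(A) tail stays open as a candidate explanation. Sequencing depth is argued against, since the totals of 3 of the 3 libraries lay inside the range of the other 9. Between nanoparticle and vehicle lungs the 5 RNAs differed by −1.41 (exact two-sided permutation p = 0.0857), and with CT010467.1 as a covariate edgeR called 0 genes there (342 at an unadjusted p under 0.05). As CT010467.1 was higher in 3 of the 4 vehicle libraries, this covariate takes up part of the group difference whatever its cause. The score of the 5 RNAs was 0.885 ± 0.999 with vehicle and −0.359 ± 0.86 at day 14, so it differed in that comparison too.

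The 8 libraries of each comparison can be split into 4 and 4 in 35 ways. Only the real split gave 1845 genes for vehicle against day 14 (highest other 0) and 2636 for nanoparticle against day 14 (highest other 135). This argues against chance (exact permutation p = 0.0286, the smallest 35 splits can give). For nanoparticle against vehicle the real split called 0 genes (762 at an unadjusted p under 0.05), so 35 of 35 splits gave at least as many by construction (highest other 0), which says nothing about chance. For camera's list counts chance cannot be excluded in any comparison. As many lists were called in 33 of 35 splits for nanoparticle against vehicle (13 real, 32 highest other), in 2 of 35 for vehicle against day 14 (26 and 26) and in 11 of 35 for nanoparticle against day 14 (23 and 32).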
